A study of Homo sapiens with 3 samples.

How the data were processed

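RNA-seq libraries of HaCaT keratinocytes were compared in 3 groups of 1 library each: control, CB at 25 µg/mL and S1650b at 50 µg/mL, each for 24 h. Per the labels, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. Whether the counting used the strand is not given in the sources used here, so antisense and overlapping genes are uncertain. The deposited count table holds counts per Ensembl gene for each library, which are whole numbers. The deposited FPKM table holds FPKM values by the authors. Counts divided by FPKM gave the same gene length in each library apart from 1 factor per library, and the library sizes this implies relative to the control are 0.972 (CB) and 1.14 (S1650b). The submitters' processing notes name CASAVA 1.7 and the genome builds mm8 and mm9, which are mouse builds and conflict with the human gene identifiers. The aligner, the counting tool and the build used are not given in the sources used here. All 58735 gene identifiers occur in GENCODE 29, from which positions on GRCh38, lengths and gene types were taken, and symbols for 58207 came from a gene name table.

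The total count was 20658247 in the control, 20946139 in CB and 20417744 in S1650b. TMM factors from edgeR 4.0.16 in R 4.3.3 were 0.956, 0.957 and 1.09. Genes with at least 1 CPM in at least 1 library were kept (14619). Each fold is the ratio of TMM-scaled CPM with an exact 95% conditional binomial (Clopper-Pearson) interval. No test across libraries was possible with 1 library per group, and no P value is given. The size rule was a fold of at least 2 with the interval on that side of 1, and for list members a fold of at least 1.5. A count of 0 was set to a floor of 3 counts for a bound, and 0.5 counts were added before log2. The 38 gene lists (34 pathways and gene families and 4 sets of markers of other cell types) were written before the data were examined, as were the comparisons, the size rules and most alternatives. The median log2 fold of each of the 34 lists was ranked among 10000 random lists of equal size matched on 20 bins of expression, and lists at a percentile of at most 2.5 or at least 97.5 stand apart. Marker sets got values only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, with a random seed of 7.

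Named genes were the 15 highest and 15 lowest against the control, and the 8 highest and 8 lowest for S1650b against CB, ranked by the interval end nearest to 1. Up to 4 members per list that passed the list rule were added, and a fixed set of barrier, stress and cytokine genes. The text names a part of them, and some genes that the rule picks are not reported here. In S1650b against control, AHRR, ATR, TP53BP1 and DDB2 lie outside this rule and were chosen after their values were seen, as was MKI67 in the plot of gene levels. Simulations of no effect drew 20 sets of counts, with an assumed coefficient of variation between cultures of 0, 10 or 20%.

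The pipeline was tested on simulated data of 14619 genes with counting error only, of which 200 were changed, 50 at each fold. For CB against control, 4% passed the size rule at a fold of 1.5, 90% at 2.5, 98% at 4 and 98% at 8, with 0.347% of unchanged genes. For S1650b against control the shares were 2, 92, 98 and 100%, with 0.243% unchanged, and for S1650b against CB 6, 94, 100 and 100%, with 0.270%. Intervals covered the true fold in 95.7, 95.8 and 95.0% of all simulated genes, changed and unchanged. Of 100 lists with no shift, 6 stood apart, and 20 of 20 lists of 20 genes shifted 1.5-fold did. A planted trend with length and GC (rho 0.567 and −0.855) was removed to −0.00157 and −0.000265.

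Alternatives were scaling by total counts, median of ratios (DESeq2 1.42.0) and upper quartile, the deposited FPKM with 0.1 added, 5 counts added, no filter or 5 CPM, 10 CPM for the correlation of folds, folds of 1.5 or 3, protein-coding genes, equal depth, no mitochondrial genes and removal of the trend with length (lowess, span 30%). Removal of the GC trend, alone or with length, was chosen after seeing the data. GC was known for 14613 of the 14619 genes.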

Results

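RNA was sequenced from HaCaT cells, an immortalised human keratinocyte line, in 3 libraries. The control culture had no particles, the CB culture received carbon black at 25 µg/mL and the remaining culture received S1650b, a particulate sample, at 50 µg/mL, each for 24 h in serum-free medium. Each group holds 1 library, so there are no replicates and no difference reported here has a replicate check. The libraries hold 20658247 (control), 20946139 (CB) and 20417744 (S1650b) gene counts, in 23790, 23005 and 25475 genes with at least 1 count. Of the 58735 genes, 14619 reached 1 CPM (counts scaled to library size) in at least 1 library, 12196 of them protein-coding. Folds are ratios of scaled CPM, and their 95% intervals cover counting error only, not variation between cultures. Reads amplified by PCR without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. A gene is counted as higher or lower when its fold is at least 2 and its interval lies on that side of 1. For members of a gene list the fold is at least 1.5. A list stands apart when its median log2 fold lies outside the middle 95% of random lists of equal size and expression. Of the 34 lists, chance would place 1.7 apart in each comparison if their members were unrelated genes. That figure does not measure variation between cultures, in which members of a list can move together, so more lists may stand apart without a treatment effect. Some of the named genes share sequence or exons with a neighbour, and that limit is given beside a part of them only. Among the rest, exons of other genes overlap 20.7% of IL6, 19.9% of SERPINB2, 18.1% of MT1X and 17.7% of NQO1.

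The series asks how DNA damage, oxidative stress and the epidermal barrier are connected in keratinocytes exposed to particulate matter and carbon black. The comparison of CB with the control asks what carbon black at 25 µg/mL does. In the CB library, 250 genes were higher and 809 lower than in the control. The list medians of the aryl hydrocarbon receptor (AHR) pathway, of keratinocyte differentiation and of the interferon response were lower than those of matched random lists. The list medians of the immediate early response, the amino acid response, the heat shock response and cholesterol synthesis were higher. In each of these lists other than the immediate early genes, most members passed the rule in neither direction. In all, 12 lists stood apart as higher and 9 as lower.

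Genes of xenobiotic metabolism were among those lower in the CB library. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610, GRCh38), a P450 enzyme that oxidises polycyclic aromatic hydrocarbons and is switched on by AHR, was 23.7-fold lower (13.0 to 48.1), with 11 counts against 257. CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902), another AHR-driven P450, was 9.92-fold lower (7.96 to 12.5). Within the AHR and xenobiotic list, 7 of 17 measured members were lower and 0 were higher, with a median log2 fold of −0.47 (percentile 0 of the random lists). ALDH3A1, an aldehyde dehydrogenase, was 3.75-fold lower (3.64 to 3.85), and ALDH1A3, which makes retinoic acid, was 2.58-fold lower. Exons of other genes overlap 28.6% of ALDH1A3.

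Oxidative stress genes of the NRF2 target list leaned higher in the CB library (6 higher, 1 lower, 26 neither of 33, median 0.31, percentile 100). SLC7A11 (ENSG00000151012), the cystine importer, was 2.12-fold higher (1.88 to 2.38), AKR1C1, an aldo-keto reductase, 1.82-fold, and GCLM, a subunit of the enzyme that starts glutathione synthesis, 1.69-fold. NQO1, a quinone reductase, had a fold of 1.31 (1.27 to 1.35). HMOX1, heme oxygenase, had 19 counts against 18 and a fold of 1.04 (0.517 to 2.10), so a difference was not detectable at this depth. Other antioxidant enzymes did not stand apart (0 of 17 higher, 0 lower, median 0.08, percentile 67.8).

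Among DNA damage genes, the repair list had a median log2 fold of 0.19 (percentile 99.8), yet only 1 of 40 members was higher and 1 lower. LIG3, a DNA ligase, was 1.54-fold higher and NEIL1, a DNA glycosylase, 2.002-fold lower, but other genes overlap 30.5% of the exons of each. Targets of p53 did not stand apart (2 higher, 3 lower of 25, median −0.02, percentile 31.0). CDKN1A, the p21 cell cycle inhibitor, had a fold of 1.13 (1.05 to 1.22) and GADD45A 1.49 (1.41 to 1.58). Lower members were TP53INP1, a regulator of autophagy and cell death (7.02-fold), and BTG2, an antiproliferative gene (4.28-fold), while AEN, a nuclease, was 2.004-fold higher.

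Barrier genes leaned lower with CB. Of 43 listed cornified envelope genes only 18 reached 1 CPM in any library, and of these 7 were lower and 0 higher (median −0.42, percentile 0). IVL, which encodes the envelope protein involucrin (ENSG00000163207, chromosome 1, 152908545 to 152911886), was 4.25-fold lower (3.73 to 4.84). TGM1, the transglutaminase that crosslinks the envelope, was 2.49-fold lower, and FLG, filaggrin, 1.59-fold lower (1.30 to 1.95). Suprabasal genes had 3 lower and 1 higher of 15 (median −0.39, percentile 0). KRT1, a keratin of differentiating cells, was 15.6-fold lower (6.42 to 49.5) on 5 counts against 77, KRT4 5.22-fold lower and KRT13 3.76-fold lower. KRT10 had a fold of 1.12. Junction genes had 5 lower and 1 higher of 24, with a median of −0.11 at percentile 3.50. TJP3, a tight junction scaffold, was 3.82-fold lower and CLDN1, a tight junction claudin, 1.87-fold lower (1.83 to 1.90), while OCLN had a fold of 1.00 and TJP1 of 1.33. Barrier lipid genes did not stand apart (2 higher, 5 lower of 20, percentile 10.9), nor did basal genes (0 higher, 1 lower of 15, percentile 29.3), in which KRT15, a basal keratin, was 2.73-fold lower. KRT8 and KRT18, keratins of simple epithelia, were 1.76-fold and 1.64-fold higher, in a list with 2 higher and 0 lower of 8 (percentile 99.7).

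Immediate early genes had 12 higher and 0 lower members of 22 (median 0.67, percentile 100). FOSL1 (ENSG00000175592, chromosome 11, 65892049 to 65900573), a subunit of the transcription factor AP-1, was 3.99-fold higher (3.72 to 4.28), FOSB 3.09-fold and JUN 2.90-fold. Ligands of the EGF receptor had 4 higher and 1 lower of 7 (median 0.70, percentile 100), among them AREG at 4.94-fold (3.90 to 6.31) and NRG1 at 2.64-fold. The amino acid response list had 8 higher and 0 lower of 21 (median 0.51, percentile 100), with CHAC1, which breaks down glutathione, at 7.60-fold (5.11 to 11.7), PSAT1, of serine synthesis, at 3.20-fold, and STC2 at 2.75-fold. Heat shock proteins had 6 higher and 0 lower of 15 (median 0.42, percentile 99.99). The near-identical pair HSPA1A and HSPA1B, with counts summed, differed little (9428 counts against 8095, fold 1.15, 1.11 to 1.18). HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910), an inducible HSP70, had 113 counts against 0, at least 37.1-fold higher with the control set at its floor of 3 counts (the exact interval starts at 29.7), and HSPA8, the constitutive HSC70, was 2.17-fold higher. Cholesterol synthesis had 7 higher and 0 lower of 25 (median 0.44, percentile 100), led by HMGCS1 at 2.42-fold, and fatty acid synthesis 4 higher and 0 lower of 14 (median 0.39, percentile 100), including FASN at 1.59-fold. DNA replication genes had 5 higher and 0 lower of 28 (median 0.31, percentile 100), and mitosis genes 1 higher and 0 lower of 26 (median 0.23, percentile 99.8).

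Interferon response genes were lower with CB in 11 of 28 members and higher in 0 (median −0.48, percentile 0), including RSAD2, an antiviral enzyme, at 3.03-fold lower and OASL at 2.23-fold lower. Alarmins and antimicrobial peptides had 5 lower and 0 higher of 10 (median −0.52, percentile 0.46), with S100A7 2.63-fold lower. The NF-kB and cytokine list went both ways (6 higher, 4 lower of 26, percentile 94.9). CXCL8, a neutrophil chemokine, was 3.11-fold higher (2.62 to 3.70) and IL1B 1.75-fold higher, while TNFAIP2 was 2.28-fold and PTGS2, the inducible cyclooxygenase, 1.51-fold lower. IL6 had 19 counts against 11 and an interval of 0.770 to 3.96. Replication-dependent histones had 6 lower and 1 higher of 10 (median −0.69, percentile 0.07). Ribosomal protein genes had 0 members higher or lower of 42, but their median of −0.18 lay at percentile 0.05.

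Other genes picked for the size of their difference in the CB library included HS3ST2, a heparan sulfate sulfotransferase (4.67-fold higher), ANXA10, an annexin (9.43-fold higher on 67 counts against 7), TNC, a matrix glycoprotein (3.92-fold higher), FST, which binds activin (3.56-fold higher), and PRODH, proline dehydrogenase (21.5-fold lower on 7 counts against 148). ALPG, an alkaline phosphatase, was 7.77-fold lower, PIK3IP1, an inhibitor of PI3 kinase, 6.19-fold lower, and TNFSF10, the death ligand TRAIL, 5.80-fold lower. SMN1 and U2AF1 each have a near-identical copy (SMN2 and U2AF1L5), so the copy the reads came from is uncertain. With the copies summed the folds were 2.91 and 2.87. DCN, a fibroblast marker also counted in the control, was 7.08-fold lower (153 counts against 1067), and COL3A1, another, 1.91-fold lower, while the fibroblast marker COL1A2 had 0 counts in the control and 5 in CB, and COL1A1 had 120 and 106. The endothelial marker CDH5 was 2.04-fold lower (503 counts against 1013), VWF, another, 1.51-fold lower, and PMEL, a melanocyte marker, 1.55-fold lower. Some markers of these cell types went the other way: EGFL7 had 88 counts against 70, MITF 97 against 90, CLDN5 10 against 0 and ERG 9 against 0. With no treatment effect and an assumed variation between cultures of 20%, simulated counts gave up to 266 genes higher and 255 lower. The 250 genes higher with CB do not exceed that level while the 809 lower do. The simulation varied each gene on its own, at a level not estimated from replicates. It therefore cannot tell whether cultures in which many genes move together would give 809. The CB count moves by over 1.5 times with the expression filter, with 77 higher and 290 lower at 5 CPM.

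**Figure D1:**
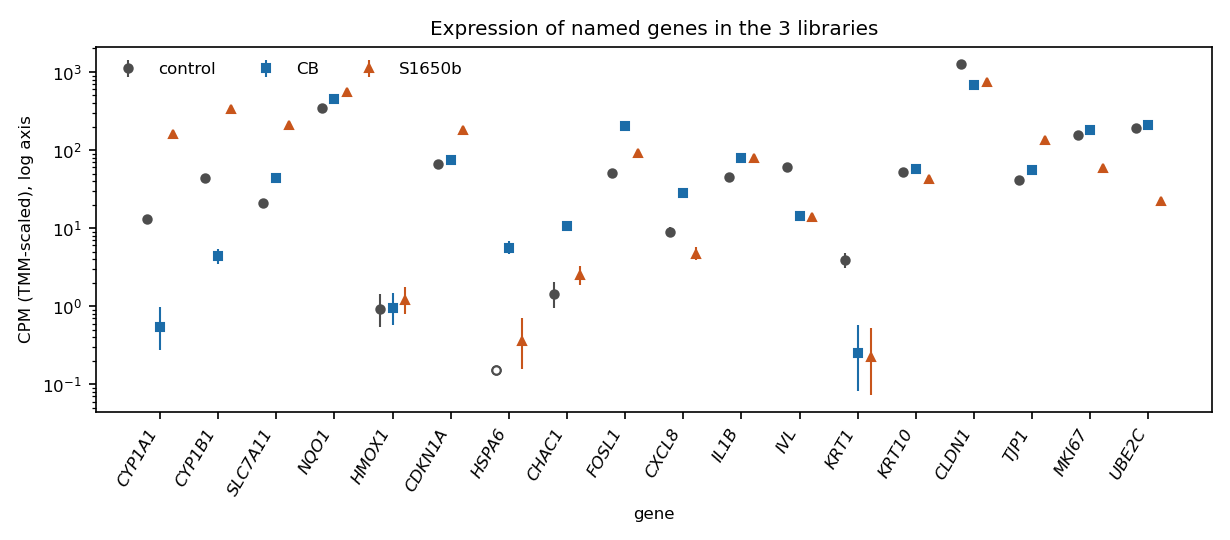
Scaled CPM (log axis) of 18 genes in the control, CB and S1650b libraries, 1 point per library with exact Poisson 95% bars for counting error, and an open marker where the count was 0 and the floor of 3 counts is drawn. CYP1A1 had 11 counts in CB, 257 in the control and 3564 in S1650b.

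The comparison of S1650b with the control asks what this particulate sample at 50 µg/mL does. In the S1650b library, 1775 genes were higher and 1149 lower. Most mitosis, DNA replication and nuclear respiratory chain genes measured were lower, as were most alarmins, and 10 of 17 AHR and xenobiotic genes were higher. The median of the NRF2 targets was higher than in matched random lists, and the medians of DNA repair and the interferon response were lower, with members of each in both directions. The library also differed from the control by gene length and base content: the median log2 fold was −0.30 in the shortest eighth of genes and 0.49 in the longest, and 0.60 in the eighth with the lowest GC content and −0.42 in that with the highest. In CB the same ranges were −0.09 to 0.01 and 0.06 to −0.07. Folds of single genes in the S1650b comparisons include these trends unless their removal is stated, so part of such a fold may follow length or GC content. Of the 1775 higher genes, 816 were still at least 2-fold higher with both trends removed. Of the 34 lists, 8 stood apart as higher and 10 as lower.

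**Figure D2:**
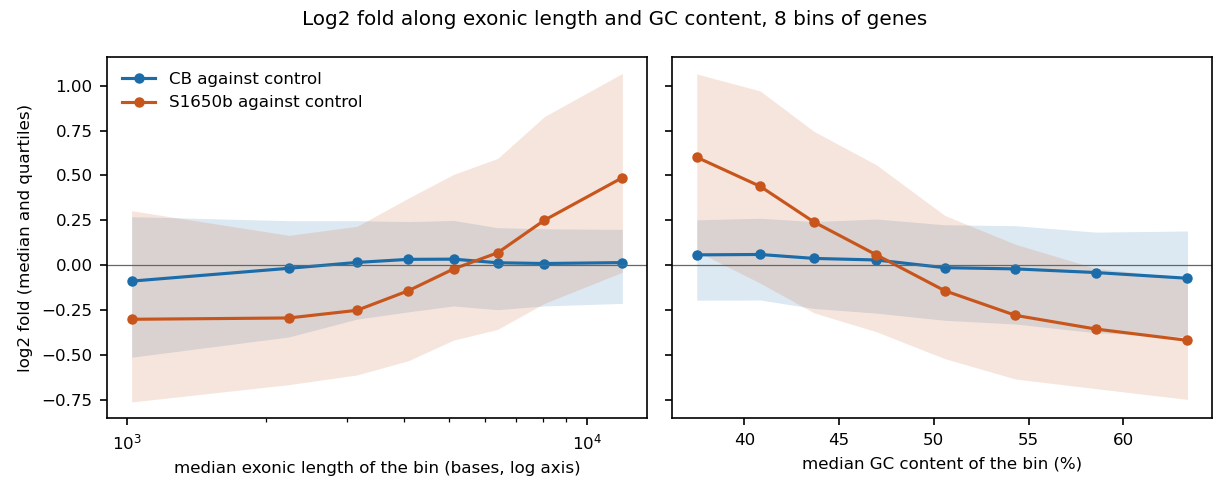
Median (points) and quartiles (shaded bands) of the log2 fold against control in 8 bins of genes, by exonic length in bases (log axis) and by GC percent, for the CB and S1650b libraries. Medians for S1650b run from −0.30 to 0.49 with length and from 0.60 to −0.42 with GC, and those for CB stay between −0.09 and 0.06.

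CYP1A1 was 12.3-fold higher in the S1650b library than in the control (10.8 to 13.99) and CYP1B1 7.81-fold higher (7.28 to 8.39). The AHR and xenobiotic list had 10 higher and 2 lower of 17 (median 0.66, percentile 99.9). TIPARP, an AHR target that limits AHR signalling, was 2.93-fold higher and AHRR, the AHR repressor, 2.31-fold higher, while SERPINB2 was 2.97-fold lower. NRF2 targets had 16 higher and 2 lower of 33 (median 0.57, percentile 100). SLC7A11 (chromosome 4, 138164097 to 138242349) was 10.1-fold higher (9.13 to 11.2), NMRAL2P, a transcribed pseudogene, 4.47-fold, TXNRD1, thioredoxin reductase, 3.43-fold (3.34 to 3.53), GCLM 2.13-fold and NQO1 1.58-fold (1.53 to 1.63). HMOX1 had 27 counts against 18, with an interval of 0.705 to 2.56. Other antioxidant enzymes had 0 higher and 6 lower of 17 and did not stand apart (median −0.41, percentile 12.1). PRDX2, a peroxiredoxin, was 1.94-fold lower.

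DNA repair genes had 17 lower and 7 higher of 40 (median −0.41, percentile 0.14). The RNA of H2AX, a histone variant, was 4.40-fold lower (4.18 to 4.63). NEIL3, a glycosylase, was 5.32-fold lower, LIG1, the replicative DNA ligase, 3.72-fold and UNG, uracil glycosylase, 2.96-fold. Mitosis and DNA replication genes were lower in the same library, and the repair genes were not tested apart from them. ATR, a damage-sensing kinase, was 2.11-fold higher and TP53BP1, a break-repair factor, 2.79-fold higher. The p53 targets had 8 higher and 6 lower of 25 (median 0.27, percentile 94.6), and with the length trend removed the p53 target genes stood apart as higher (percentile 99.3). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) was 2.71-fold higher (2.55 to 2.89), ZMAT3, an RNA-binding protein, 3.38-fold, RRM2B, a ribonucleotide reductase subunit, 2.70-fold and GADD45A 1.92-fold. DDB2, a sensor of ultraviolet damage, was 2.13-fold lower.

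Mitosis genes were lower in 26 of 26 members (median −1.52, percentile 0) and DNA replication genes in 24 of 28, with 1 higher (median −1.45, percentile 0). UBE2C, which helps degrade mitotic cyclins, was 8.63-fold lower (7.85 to 9.50), PLK1, a mitotic kinase, 7.28-fold, AURKB, another, 7.01-fold and SPC24, a kinetochore protein, 13.1-fold (10.0 to 17.6). E2F2, a transcription factor of S phase entry, was 7.06-fold lower and CDC45, part of the replicative helicase, 5.36-fold lower. Nuclear genes of the respiratory chain had 20 lower and 0 higher of 26 (median −0.80, percentile 0), with CYC1, cytochrome c1, 2.30-fold lower. Ribosomal protein genes had 26 lower and 0 higher of 42 (median −0.66, percentile 0.01), such as RPL35 at 1.84-fold, but with the length trend removed the cytoplasmic ribosomal proteins had a median of −0.51 at percentile 4.52. Random lists matched to these genes had medians of −0.54 to −0.23, so genes of like expression were lower too. Reference genes had 5 lower and 1 higher of 12 and did not stand apart (median −0.48, percentile 13.8). Mitochondrially encoded genes had 0 members higher or lower of 13. Their median of −0.02 lay at percentile 98.4, above matched lists though not above 0, and scaling by total counts turned its sign.

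Barrier genes in the S1650b library went both ways. Cornified envelope genes had 8 lower and 1 higher of 18 (median −0.45, percentile 1.61): PI3, elafin, was 8.94-fold lower, TGM1 5.11-fold lower and IVL 4.48-fold lower (3.95 to 5.09). With length and GC trends removed the cornified envelope and late differentiation list no longer stood apart (percentile 11.1). FLG had a fold of 1.24 (1.05 to 1.46), which turned below 1 with the length trend removed. Suprabasal genes did not stand apart (4 higher, 5 lower of 15, median −0.12, percentile 88.4). KRT1 was 17.4-fold lower on 5 counts against 77 and KRT13 5.14-fold lower, while the desmosomal cadherin DSG2 was 2.65-fold higher. KRT10 was 1.22-fold lower, a direction that turned with length and GC trends removed. Basal genes stood apart as higher (median 0.21, percentile 99.97), although 4 members were higher and 4 lower of 15. DST and LAMA3, which anchor basal cells to the basement membrane, were 4.17-fold and 3.15-fold higher, and KRT5 and KRT14, the basal keratin pair, were 3.14-fold and 2.89-fold lower. Junction genes had 7 higher and 5 lower of 24 (median 0.44, percentile 99.96), and with length and GC trends removed the tight and adherens junctions list lay at percentile 96.4. TJP1, the scaffold ZO-1, was 3.24-fold higher (2.995 to 3.50), PATJ, a polarity protein, 3.20-fold higher, CLDN1 1.68-fold lower and NECTIN1 2.51-fold lower. OCLN had a fold of 1.39, which turned below 1 with the GC trend removed. Barrier lipid genes did not stand apart (4 higher, 3 lower of 20, percentile 69.4).

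Cholesterol synthesis had 6 higher and 1 lower of 25 and a median of 0.05 at percentile 98.6, a median that turned negative with upper quartile scaling. MSMO1, an enzyme of the pathway, was 2.51-fold higher. Fatty acid synthesis had 5 higher and 2 lower of 14 (median 0.31, percentile 99.2), and with the length trend removed fatty acid synthesis lay at percentile 97.3, just inside the random range. Its members GPAM and LPIN1, which make glycerolipids, were 3.45-fold and 2.60-fold higher, and SREBF1, which encodes their regulator, was 2.09-fold lower. Heat shock proteins had 4 higher and 3 lower of 15 (median 0.15, percentile 97.9), a median that turned negative with the GC trend removed. HSPH1 was 2.25-fold higher and HSPA8 1.56-fold lower. Immediate early genes had 7 higher and 0 lower of 22 (median 0.16, percentile 96.1), including FOSB at 4.39-fold, ATF3 at 3.63-fold and JUN at 3.17-fold. With the length trend removed the immediate early and AP-1 list stood apart as higher (percentile 99.9). The amino acid response list had 3 higher and 7 lower of 21 (median −0.41, percentile 7.83), with PHGDH, of serine synthesis, 2.84-fold lower.

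Alarmins and antimicrobial peptides had 9 lower and 1 higher of 10 (median −2.04, percentile 0), with S100A9, a calprotectin subunit, 5.67-fold lower (4.75 to 6.81) and S100A8 5.95-fold lower. Interferon response genes had 14 lower and 2 higher of 28 (median −0.58, percentile 0), including OASL at 4.96-fold and ISG15 at 2.74-fold lower. In the NF-kB and cytokines list 12 were lower and 2 higher of 26 (median −0.34, percentile 2.48), but the call ended when counts were thinned to equal depth (percentile 2.51) and with the length trend removed (percentile 5.48). CXCL3, a chemokine, had 0 counts against 32, at least 12.1-fold lower at the floor of 3 counts (the exact interval starts at 9.24). CXCL8 was 1.90-fold lower and IL1B 1.71-fold higher. IL6 had 25 counts against 11 and an interval of 0.955 to 4.53, and PTGS2 a fold of 1.42 that turned below 1 with the GC trend removed. Signals to melanocytes and lipid mediators had 6 lower and 2 higher of 13 (median −0.56, percentile 0.78), and with the length trend removed the melanocyte-keratinocyte signals and lipid mediators list lay at percentile 3.17.

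ITGA2, a collagen receptor subunit, was 4.95-fold higher and CALD1, which binds actin, 6.40-fold higher. ITGB6, an integrin subunit, was 5.69-fold higher, with 20.6% of its exons overlapped by another gene. LYPD2 was 65.5-fold lower (4 counts against 232), CRABP2, which binds retinoic acid, 15.1-fold lower, and the fibroblast markers DCN and COL3A1 29.4-fold and 8.68-fold lower, while COL1A1, another such marker, had 156 counts against 120 (6.99 and 6.08 CPM). Among melanocyte markers PMEL was 2.66-fold lower, MITF was 1.51-fold higher (1.15 to 1.98) and MLANA had 17 counts against 3, and the endothelial marker CDH5 had 920 counts against 1013. Scaling by total counts moved the median gene by 0.19 log2, and by upper quartile by −0.12, so the share of differing genes that were higher was 60.7% as reported, 75.3% with total counts and 48.8% with upper quartile scaling. With length and GC trends removed the genes higher numbered 1080 in place of 1775, of which 816 were in both sets, and 778 of the 1149 lower genes were lower there too.

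**Figure D3:**
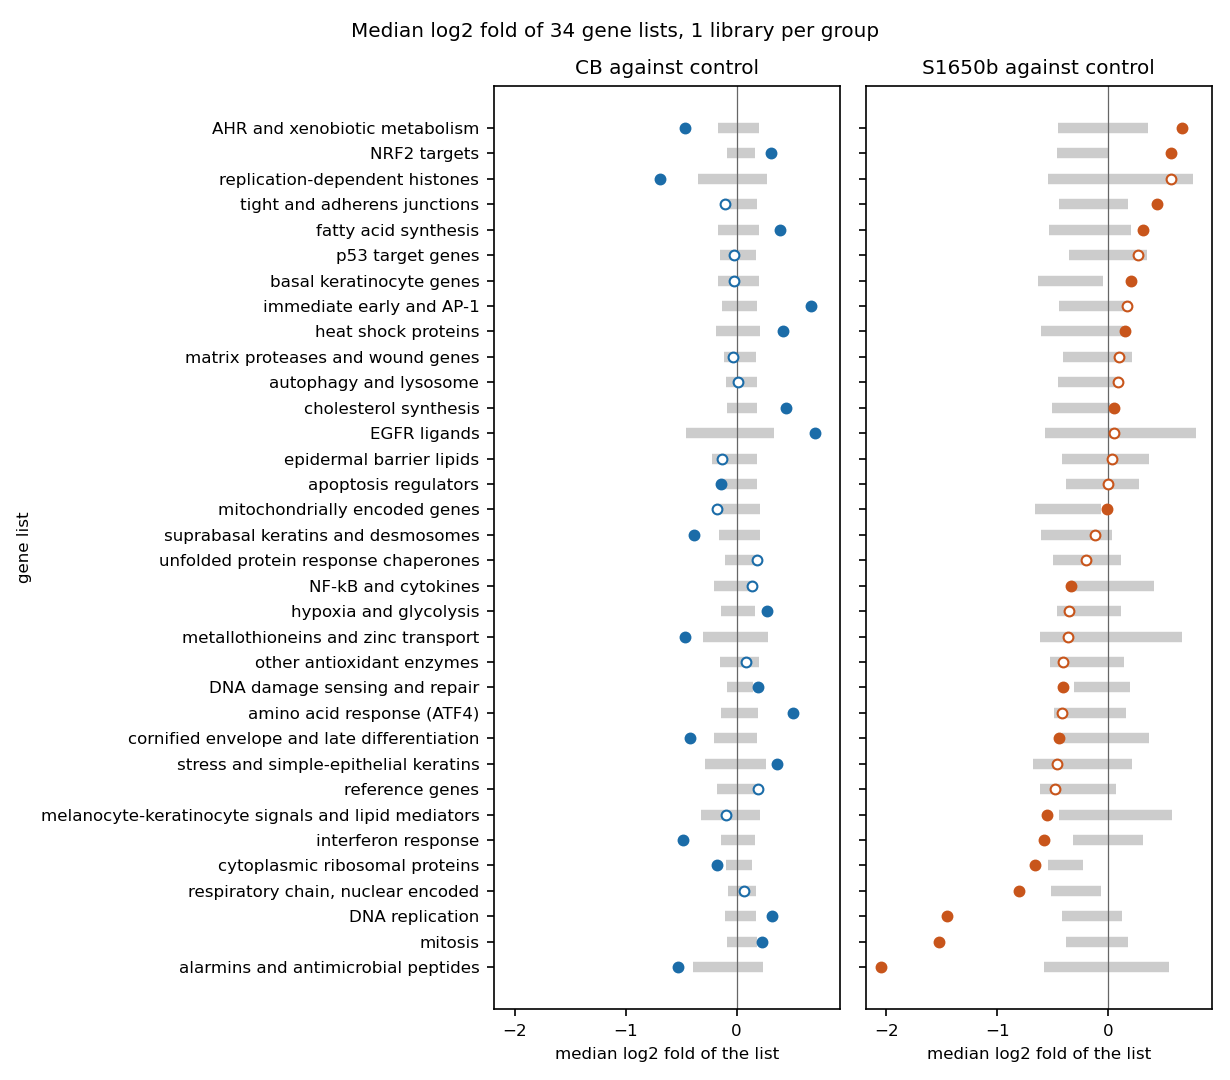
Median log2 fold against control of 34 gene lists in the CB and S1650b libraries, with grey bars for the middle 95% of matched random lists and filled markers for lists outside that range. Mitosis lies at 0.23 in CB and −1.52 in S1650b, and the AHR list at −0.47 and 0.66.

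The comparison of S1650b with CB sets the treated libraries side by side, at doses that differ (50 and 25 µg/mL), so material and dose are not separated. In S1650b, 2310 genes were higher and 1395 lower than in CB. Most AHR and xenobiotic genes measured were higher in S1650b, and most genes of the cell cycle, the amino acid response, the EGF receptor ligands and the alarmins were lower. CYP1A1 was 291-fold higher (163 to 584) and CYP1B1 77.5-fold higher (62.8 to 96.7), in a list with 11 higher and 3 lower of 17 (median 1.27, percentile 100). NRF2 targets had 6 higher and 2 lower of 33 (median 0.25, percentile 99.98), with SLC7A11 4.77-fold and TXNRD1 2.82-fold higher. Other antioxidant enzymes had 9 lower and 1 higher of 17 (median −0.63, percentile 1.15), and with the length trend removed the other antioxidant enzymes lay at percentile 18.0.

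Cell cycle genes were lower in S1650b than in CB in 26 of 26 mitosis members (median −1.67, percentile 0) and 25 of 28 replication members, with 0 higher (median −1.95, percentile 0). PLK1 was 9.31-fold lower and CDC45 8.24-fold lower. DNA repair genes had 20 lower and 6 higher of 40 (median −0.55, percentile 0.01), with H2AX 5.02-fold lower, and nuclear respiratory chain genes 22 lower and 0 higher of 26 (median −0.81, percentile 0). The p53 list did not stand apart (9 higher, 5 lower of 25, percentile 92.1), but with length and GC trends removed the p53 target genes lay at percentile 99.6. CDKN1A was 2.41-fold higher, TP53INP1 18.5-fold, and BMF, which promotes cell death, 20.36-fold.

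Amino acid response genes had 14 lower and 2 higher of 21 in S1650b relative to CB (median −1.08, percentile 0), with STC2 4.24-fold and PHGDH 3.94-fold lower. EGF receptor ligands had 4 lower and 1 higher of 7 (median −1.04, percentile 0.11), among them AREG at 2.33-fold lower. Alarmins had 8 lower and 2 higher of 10 (median −1.41, percentile 0), and NF-kB and cytokine genes 12 lower and 3 higher of 26 (median −0.43, percentile 0.38), with CXCL8 5.91-fold lower. With length and GC trends removed the NF-kB and cytokines list lay at percentile 3.77. Junction genes had 10 higher and 1 lower of 24 (median 0.44, percentile 99.9), with TJP1 2.44-fold higher. CLDN1, at 1.11, and OCLN, at 1.39, both turned below 1 with the GC trend removed. Basal genes went both ways, with 5 higher, 2 lower and 8 neither of 15 (median 0.13, percentile 99.6), and the median turned negative with the length trend removed. DST was 3.50-fold higher, and KRT14 and KRT5 were 2.80-fold and 2.67-fold lower. Cornified envelope genes did not stand apart (3 higher, 8 lower of 18, percentile 14.6), and neither did suprabasal genes (5 higher, 1 lower of 15, percentile 91.6), whose median was −0.06 and mean 0.19. IVL was 1.06-fold lower (0.895 to 1.24), a difference not detectable at this depth, and FLG was 1.97-fold higher. Mitochondrially encoded genes had 2 higher and 0 lower of 13 (median 0.16, percentile 99.6), a median that turned negative with the GC trend removed. HSPA6 was 15.7-fold lower (8 counts against 113) and VEGFA, the vascular growth factor, 2.87-fold lower. The share of differing genes that were higher was 62.3% as reported, 76.6% with total counts and 53.4% with upper quartile scaling.

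Both treatments were compared with the same control library, so an error in that library enters both sets of folds. Across 14619 genes, which are not independent replicates, the log2 folds of CB and S1650b had a Pearson r of 0.166, a Spearman rho of 0.0616 and a covariance of 0.0835. Among genes of at least 10 CPM the Pearson r was 0.0676. With no effect and a shared control, simulated counts gave r of 0.515, 0.511 and 0.505 and covariance of 0.0230, 0.0445 and 0.110 at an assumed variation between cultures of 0, 10 and 20%. Genes higher in both numbered 85, against 30.4 for independent lists and at most 76 in the simulation at 20%. Genes lower in both numbered 214, against 63.6 and at most 39. IVL, TGM1, KRT1 and KRT13 were lower in both treated libraries, and JUN, FOSB, SLC7A11 and HMGCS1 were higher in both. Genes lower with CB and higher with S1650b numbered 60, against 98.2 for independent lists but at most 1 in the shared-control simulation at 20%. The opposite held for 15, against 19.7 for independent lists and at most 0 in that simulation. The simulated lists held at most 266 genes higher and 255 lower in CB, and 272 and 278 in S1650b. The observed lists, other than the 250 genes higher in CB, were far longer, and longer lists overlap more. Independent lists in turn leave out the shared control. Neither benchmark therefore tells whether the overlaps are more or less than such lists would give.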

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

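The tests of scaling and of shared reads, the YAP list and the removal of the GC trend were chosen only after the results they bear on were seen. The YAP list took the place of an earlier test of cornified, suprabasal and replication genes in CB, whose outcome had been seen to favour a denser control.

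Several genes went opposite ways in the treated libraries, each by at least 2-fold against the control, and the differences between treatments were not tested. There were 60 genes lower with CB and higher with S1650b, and 15 the other way. As S1650b over CB, CYP1B1 had a fold of 77.5 and CYP1A1 of 291. The antisense gene CYP1B1-AS1 had a fold of 18.2, with 7 counts in CB. KLHL24, a ubiquitin ligase adaptor, had a fold of 8.32, SESN3, a stress-induced regulator of mTOR signalling, 9.36, BMF 20.36, TP53INP1 18.5, SLITRK6 16.3 and ABCA12, the lipid transporter of the epidermal barrier, 5.88. Lower in S1650b were FST, with a fold of 0.0926, TNC, with 0.122, and U2AF1, with 0.0430. U2AF1 has a near-identical copy, U2AF1L5, so its value is uncertain. With both copies summed the fold was 0.222 for S1650b over CB and 0.638 for S1650b over the control, which is short of 2-fold lower, so the opposite direction by that rule does not hold for the sum.

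Mitosis and DNA replication genes were lower in the S1650b library than in the control, with a median log2 fold of −1.46 over 54 members. The tables argue against a length and GC trend as the whole cause, since the median was −1.69 after its removal, with 53 members below 0 by any amount. The other scalings shift all genes alike, by 0.19 log2 at most, so the median could move only as far as −1.27. The choice among these scalings thus does not account for the pattern, but this is not a separate test. An effect of S1650b may account for the pattern, as may a difference between the cultures or library preparations, which 1 library per group leaves open.

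Ribosomal protein and nuclear respiratory chain genes were lower in S1650b, with a median of −0.68 over 68 members. After the length and GC trends were removed it was −0.54 at percentile 0 (random lists −0.35 to −0.12), with 67 members below 0 by any amount. This argues against the trends as the whole cause. Removal of the length trend alone ended the call for the cytoplasmic ribosomal proteins (from −0.66 at percentile 0.01 to −0.51 at 4.52, as the median moved towards 0), so part of their difference may follow length. The other scalings shift all genes alike, so the median could move only as far as −0.48 under them, which is not a separate test. The treatment and a culture difference stay open.

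CYP1A1 and CYP1B1 were lower in CB, and the tables argue against a length and GC trend (the higher fold was 0.0988 after its removal). Few reads were assigned to the related genes: CYP1A2 had 0 counts in CB and in the control, and CYP1B1-AS1 had 7 and 21. The summed folds therefore could hardly change (intervals ending at 0.131 or lower). Reads left uncounted because they match more than 1 gene are not seen in these counts, so that form of sharing was not tested. A denser or slower-growing control culture may account for part of it. Targets of YAP and TEAD, which density lowers, lay at percentile 98.5 or higher in both treated libraries, as that explanation needs. Both percentiles rest on the same control library, so they are not independent, and 2 of the 21 targets are also in the other gene lists. Whether a denser culture raises CYP1A1 and CYP1B1 was not tested. With length and GC trends removed the targets lay at 94.1 in CB and 96.8 in S1650b, inside the random range, so the support is weak. Of the 21, 6 were higher and 1 lower in CB, and 6 higher and 5 lower in S1650b. Mitosis genes, which slower growth of the control would make higher in both, had a median of 0.23 in CB and −1.52 in S1650b. An effect of carbon black stays open and was not tested apart from a denser or slower-growing control.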

How the results depend on the processing

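Removal of the GC trend, alone or with the length trend, was chosen after seeing the data. No alternative leaves a library out, because each group has 1 library, and the mitochondrially encoded genes have no value without mitochondrial genes. Of the gene counts, 62 stayed within 1.5 times the reported count and 22 moved further. Of the list medians under all alternatives, 977 kept their call, 17 gained a call, 17 lost one and 6 reversed. The sign was compared only for lists that stood apart, so the 977 can include other lists whose median changed sign. Of the named gene values, 3114 stayed inside their counting interval or very close to the reported log2 fold, 1024 moved further and 9 reversed. Genes lower in S1650b against CB numbered 929 with total counts. Genes lower in CB numbered 523 with the deposited FPKM. Genes higher in S1650b against control numbered 1159 with the GC trend removed and 1080 with length and GC trends removed. Without a filter, 429 genes were higher in CB. At 5 CPM, where fewer genes enter, 77 were higher and 290 lower in CB, and 1380 higher in S1650b against CB. At a fold of 1.5 the counts higher and lower were 710 and 1530 for CB, 3236 and 2804 for S1650b against control, and 3814 and 3036 for S1650b against CB. At a fold of 3 they were 87 and 307, 474 and 463, and 881 and 453. Among protein-coding genes alone, 151 were higher and 538 lower in CB. The median of mitochondrially encoded genes in S1650b against control was 0.18 with total counts and 0.24 with the length trend removed. That of cholesterol synthesis in S1650b against control was −0.073 with upper quartile scaling. Basal keratinocyte genes in S1650b against CB had −0.12 with the length trend removed. The median log2 fold of list heat shock proteins in S1650b against control was −0.00556 with the GC trend removed, and that of mitochondrially encoded genes in S1650b against CB −0.17. Among genes, log2 folds in S1650b against control were −0.19 for FLG with the length trend removed, and −0.024 for OCLN and −0.070 for PTGS2 with the GC trend removed. In S1650b against CB the GC trend's removal gave −0.25 for CLDN1 and −0.018 for OCLN. With length and GC trends removed, KRT10 had 0.060 and OCLN −0.051 in S1650b against control, and CLDN1 had −0.063 and OCLN −0.034 in S1650b against CB. The correlation of folds was 0.143 with 5 counts added, 0.0676 at 10 CPM, 0.139 with the deposited FPKM and 0.141 with both trends removed. Counts under looser or stricter folds and filters follow from how those settings are built. For the other values the cause was not tested. Depth limits genes with few counts, such as HMOX1 and IL6.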

Other observations

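The test of the FOXO list was chosen after genes linked to FOXO had been seen to differ, and removal of the GC trend was chosen after seeing the data.

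Median folds of non-coding gene classes are given without a comparison with matched random genes. Long intergenic RNA genes had a median log2 fold of −0.29 in CB and 0.25 in S1650b against the control, over 510 measured genes, and antisense genes had −0.26 and 0.14 over 740. Processed pseudogenes, which share sequence with their parent genes, had 0.06 and −0.42 over 371. With length and GC trends removed, the medians in CB and S1650b were −0.24 and 0.31 for long intergenic RNA genes, −0.23 and 0.30 for antisense genes and 0.16 and −0.17 for processed pseudogenes. Mitochondrially encoded genes took 4.92% of counts in the control, 4.11% in CB and 6.0% in S1650b.

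Autophagy and lysosome genes had 0 higher and 3 lower of 25 in CB and 6 higher and 3 lower in S1650b, neither list median standing apart (percentiles 30.3 and 96.4). ULK1, a kinase that starts autophagy, was 1.53-fold lower in CB than in the control and 2.58-fold higher in S1650b than in CB, and GABARAPL1, an autophagosome protein, was 1.53-fold lower and 2.61-fold higher in the same comparisons. Hypoxia and glycolysis genes stood apart as higher in CB (3 higher, 1 lower of 25, median 0.27, percentile 99.96), with VEGFA 2.29-fold higher. In S1650b against control they did not (4 higher, 6 lower, percentile 14.2), with GAPDH 1.63-fold lower. Metallothioneins and zinc transporters stood apart as lower in CB (1 higher, 2 lower of 7, median −0.47, percentile 0.36), with MT1X 1.82-fold lower. Apoptosis regulators had 3 higher and 3 lower of 24 in CB (median −0.14, percentile 1.41).

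A FOXO-dependent programme may differ between the treated libraries. The thought came from BMF, KLHL24, SESN3, TP53INP1 and PIK3IP1, which are left out of the list tested. Of the 15 listed genes, 9 were higher in S1650b than in CB and 0 were lower, with a median log2 fold of 0.77 at percentile 99.7. After length and GC trends were removed it was 0.57 at percentile 99.91. Members included FBXO32, a ubiquitin ligase of muscle wasting, with a fold of 4.59, TXNIP, a thioredoxin inhibitor, 4.31, KLF9 4.93 and RBL2, a pocket protein, 2.70, while CDKN1B had 0.737. For several members the control lay near S1650b and CB lay below both: in the control, CB and S1650b, TXNIP had 176, 50.2 and 216 CPM, KLF9 7.14, 1.55 and 7.62, and CCNG2 72.3, 35.5 and 71.2. FBXO32, with 42.3, 32.1 and 147 CPM, was higher in S1650b than in both others. The difference between the treated libraries is thus in part a lower level in CB. Of the 15, BCL2L11 and SESN1 are in lists whose values were already seen, and without them 13 members had a median of 0.88 at percentile 99.91. With 1 library per group, this remains a hypothesis about these libraries.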
